A study of Mus musculus with 24 samples.

How the data were processed

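The series holds 24 RNA-seq libraries of bone marrow-derived macrophages from wild-type C57BL/6J mice, in 8 groups of 3. The groups combine 4 treatments (untreated, 100 nM dexamethasone, 100 ng LPS in a volume that is not stated, and both together) with 2 times, 4 h and 24 h. The deposited table gives whole-number counts per gene for each library, not scaled in any way, per the file headers. Its other numeric column is the summed exon length of each gene in bases, also per the file headers, and served only to match random gene lists on length. According to its header the table was made with featureCounts 2.0.0 on read pairs, unstranded, summing exons by gene of GENCODE M29, with neither reads that match several places nor reads that overlap several genes counted. The labels name STAR for the alignment without version or settings, and list GRCm38 and mm10 as the build. GENCODE M29 is an annotation of GRCm39, and of 14910 tested genes with a position in GENCODE M21 (GRCm38) only 324 start at the same base, with Actb starting at 142888870 in the table and 142903115 in M21. Positions are given as in the table and taken as GRCm39, while the build used for the alignment stays uncertain.

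The table lists 55357 genes, of which 25771 have no count in any library. Gene symbols came from GENCODE M21 by gene identifier without version, which named 52081 identifiers and left 3276 without a symbol, holding 0.201 to 0.457% of the counts of a library. Library totals run from 18326206 to 27908164 counts. After edgeR's filterByExpr step with the 8 groups, 14985 genes were tested and 14601 with some counts fell below the filter.

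All 24 libraries entered 1 fit with a mean per group, in edgeR 4.0.16 (R 4.3.3) with TMM scaling factors (0.679 to 1.184), robust quasi-likelihood dispersions and 16 residual degrees of freedom. The biological coefficient of variation was 6.29%. Each comparison was a two-sided quasi-likelihood F test of a contrast, with Benjamini-Hochberg adjustment over the 14985 genes and a threshold of 0.05. No covariate entered the fit, since the labels give none and the replicate numbers are not said to stand for a donor or a day. Between replicates, the chi-square statistic per gene ran from 3.21 to 8.94 over the 24 pairs. Values are counts scaled by library size and TMM factor (CPM) as mean ± standard deviation of 3 libraries. Log2 fold changes carry an approximate standard error, the absolute log2 fold change over the square root of the F statistic. Where a group has few counts this can be far too small or too large. The labels do not say whether the 3 libraries of a group come from 3 mice or from 1 culture, and the p-values measure only the spread between these libraries.

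The 12 comparisons were fixed before the data were examined. They are LPS against untreated, dexamethasone against untreated and LPS plus dexamethasone against LPS, each at 4 h and at 24 h, the untreated groups at 24 h against 4 h, and 5 interactions. The interactions ask whether the dexamethasone effect under LPS, the LPS effect and the effect of dexamethasone alone differ between the times, and whether the dexamethasone effect differs with and without LPS at each time. LPS-induced and LPS-repressed genes are those called at 2-fold or more in LPS against untreated at that time. Because both comparisons share the LPS libraries, the same counts were made in 10 simulations in which dexamethasone had no effect.

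Genes named in the text follow a rule fixed before the data were examined. It takes a fixed panel of 26 genes, of which 25 were tested (Pdk4 was below the filter), then for each comparison the 5 genes with the largest rises and the 5 with the largest falls. These have adjusted p < 0.05, a mean of at least 5 CPM over the groups compared, replicates that do not overlap and a symbol that is not a provisional name. The condition on replicates was not applied to the 5 interactions. It also takes up to 2 rises and 2 falls per fixed gene list past the threshold with at least 1 CPM in a group, or failing any such gene up to 2 with the highest mean. The text names a part of these. Where a group has no count, the fold is given as at least the ratio to 3 counts over the group, and where it has 1 to 3 counts the ratio carries a 95% interval from the counts.

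The 34 gene lists were also fixed before the data were examined and were not chosen on these samples. They cover glucocorticoid targets, inflammatory cytokines, chemokines, interferon-stimulated genes, NF-kB feedback, inflammasome, Toll-like receptor 4 pathway, markers of alternative activation, uptake of apoptotic cells, MHC class II and co-stimulation, glycolysis, pyruvate dehydrogenase, tricarboxylic acid cycle, nuclear-encoded respiratory chain, mitochondrially encoded genes, arginine and nitric oxide, fatty acid oxidation, cholesterol synthesis, eicosanoids, hypoxia response, Nrf2 response, lysosome, cell cycle, circadian clock, unfolded protein response, ribosomal proteins, immediate early and heat shock genes, macrophage identity, and markers of neutrophils, dendritic cells, lymphocytes, stromal and endothelial cells, mast cells and basophils, and erythroid cells. Tested were 4 of 13 lymphocyte markers, 6 of 14 stromal and endothelial, 5 of 9 mast cell and basophil, 11 of 12 neutrophil and 8 of 8 dendritic cell markers. Summed levels also include members that were not tested. The erythroid list had 0 tested genes, with a summed level of at most 0.508 CPM. The other 33 were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Beside this stand camera with an estimated correlation, the directional fry test (limma 3.58.1), and counts of members called over all genes and over the list alone.

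Alternatives fixed before the data were examined were median-ratio (RLE) size factors, scaling by library size only, DESeq2 1.42.0, no filter, robust estimation off, only the libraries compared, replicate number as a block, leaving out each library in turn, a minimum of 2-fold, LPS genes with no fold minimum, and the other list tests. Chosen after the data were seen were fits without genes on chromosomes X and Y, fits with only the 12 libraries of a time, and counts without the genes that GENCODE M21 calls pseudogenes. Groupings were also permuted, in 10 splits of the 6 libraries for comparisons of 2 groups, 20 assignments for LPS genes and 21 for interactions, the last fitted on only the 12 libraries of the 4 groups concerned.

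A self-test drew negative binomial counts from the fitted group means and dispersions, with no dexamethasone effect under LPS except for known changes placed at 24 h. Of 200 changed genes among 14695, edgeR recovered 42 of 67 at 1.5-fold, 59 of 67 at 2-fold and 61 of 66 at 4-fold, with 8 unchanged genes called, and the interaction recovered 31, 51 and 56. In the 4 h comparison of the same simulation, where no gene was changed, it called 0. Camera called a list of 30 raised genes and did not call 30 unchanged ones.

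Because counting was unstranded, antisense reads that overlap the exons of only 1 annotated gene are counted with it. Reads that overlap several annotated genes, and reads that match several places, as those of close paralogs and pseudogenes can, are left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.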

Results

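Bone marrow-derived macrophages of wild-type C57BL/6J mice were left untreated or given 100 nM dexamethasone, 100 ng LPS or both, and sampled at 4 h and 24 h. Each of the 8 groups has 3 libraries, with 18326206 to 27908164 counts per library on 55357 genes. The labels ask how the anti-inflammatory action of a glucocorticoid under LPS depends on time, and the series title points to metabolism. The first principal component of the 24 libraries holds 51.2% of the variance and places the LPS groups of 4 h apart from all others. The second holds 25.3% and runs from untreated cells at 4 h to LPS-treated cells at 24 h. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 14985 genes tested, and those of gene lists from camera, adjusted over the 33 lists of a comparison. All levels are mean CPM ± standard deviation with n = 3 per group.

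The first question is what LPS alone did at 4 h. LPS raised 5118 and lowered 5812 genes, 2630 and 3249 of them at least 2-fold. All 18 inflammatory cytokines tested rose, with a median log2 fold change of 7.92, or 7.84 with bounded values for genes with few counts (camera adjusted p = 9.4e-35). Tnf, the classical early macrophage cytokine, went from 35.6 ± 1.59 to 2020 ± 112 CPM (log2 fold change 5.82 ± 0.08, adjusted p = 6.4e-36). Il1b, a cytokine released through the inflammasome, went from 1.1 ± 0.549 to 6550 ± 486 CPM (12.46 ± 0.15, adjusted p = 1.2e-28). Il6 had 3 counts in all untreated libraries and 28352 with LPS, a ratio of 13500 (95% interval 4630 to 65700). Nos2, the inducible nitric oxide synthase, had 2 and 100141, a ratio of 71800 (19900 to 593000). Edn1, the endothelin 1 gene, had no count in untreated cells and 540 ± 23.3 CPM with LPS, at least 13600-fold more. All 20 chemokines rose (median 8.33, camera adjusted p = 8.1e-19). Cxcl10 was at 9780 ± 556 CPM against 2.97 ± 1.05 (11.7 ± 0.19, adjusted p = 1.4e-21). All 34 interferon-stimulated genes rose (median 6, adjusted p = 7.4e-33), and all 18 genes of NF-kB feedback (median 4.48, adjusted p = 3.5e-44).

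Il10, which codes for an anti-inflammatory cytokine, also rose at 4 h, from 7.24 ± 1.23 to 363 ± 21.3 CPM (5.65 ± 0.13, adjusted p = 3.3e-23). Of the 21 glycolysis genes, 16 were higher and 4 lower (median 0.72, camera adjusted p = 3.6e-05, adjusted p = 0.26 with an estimated correlation). Pfkfb3, whose product drives glycolytic flux through fructose 2,6-bisphosphate, went from 30.4 ± 0.971 to 2350 ± 86.5 CPM (6.28 ± 0.08, adjusted p = 3.1e-35). Slc2a1, a glucose transporter, went from 55 ± 4.15 to 410 ± 16.8 (2.89 ± 0.07, adjusted p = 1.7e-28). Of 30 cell cycle genes 26 were lower and 2 higher (median -1.15, adjusted p = 8.5e-06, adjusted p = 0.29 with an estimated correlation). Among them was Mcm2, a replication licensing factor (-2.85 ± 0.07, adjusted p = 1.8e-28). Tsc22d3, the glucocorticoid-induced leucine zipper gene, fell without any added glucocorticoid, from 37.2 ± 1.47 to 1.8 ± 0.285 CPM (-4.36 ± 0.11, adjusted p = 7.9e-29). Nr3c1, the glucocorticoid receptor, rose from 98.8 ± 6.08 to 427 ± 8.56 (2.11 ± 0.06, adjusted p = 4.4e-28). The stromal and endothelial list, which holds markers of other cell types, had 5 of 6 genes higher. Its summed levels were 19.2 ± 3.68 CPM in untreated and 170 ± 25 CPM in LPS-treated cells. Neutrophil markers had 6 of 11 higher with none lower (60.8 ± 11.5 and 151 ± 24.8 CPM), dendritic cell markers 5 of 8 with none lower (28.9 ± 5.64 and 67.8 ± 12.8), and lymphocyte markers 2 of 4 lower (32.6 ± 3.42 and 23.1 ± 4.18). Mast cell and basophil markers had 3 of 5 higher with none lower (4.79 ± 0.827 and 11.1 ± 1.86). Immediate early and heat shock genes had 6 higher and 4 lower of 11, with sums of 666 ± 6.4 and 1970 ± 130 CPM. Scaling by library size only shifts all log2 fold changes here by -0.77 and leaves 2434 genes higher and 9779 lower, with the glycolysis median at -0.06.

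The second question is what LPS alone did at 24 h, where 4455 genes were higher and 4591 lower, 1544 and 2099 at least 2-fold. Tnf was at 64 ± 5.24 against 17.6 ± 1.78 CPM (1.87 ± 0.08, adjusted p = 3.4e-21) and Il1b at 3190 ± 181 against 2.14 ± 0.0443 (10.54 ± 0.14, adjusted p = 4e-27). Nos2 was at 235 ± 52 against no count, at least 5520-fold more. Saa3, an acute phase gene, reached 58400 ± 2850 CPM from 0.378 ± 0.352 (17.24 ± 0.28, adjusted p = 7.6e-20) and was the most abundant transcript of these cells. Il10 was lower, at 0.778 ± 0.308 against 4.83 ± 0.768 CPM (-2.62 ± 0.28, adjusted p = 7.1e-09). Of 21 glycolysis genes 20 rose and 1 fell (median 1.89, camera adjusted p = 1.9e-31). Ldha, lactate dehydrogenase A, was at 1920 ± 58.8 against 402 ± 30.4 CPM (2.25 ± 0.06, adjusted p = 4.4e-28). Of 14 hypoxia response genes 12 were higher (median 1.71, adjusted p = 1.2e-07). Hif1a was at 752 ± 31.2 against 72.9 ± 3.72 CPM (3.37 ± 0.07, adjusted p = 1.6e-31). Of 30 cell cycle genes 29 were lower (median -2.63, adjusted p = 3.7e-26). Of 65 nuclear respiratory chain genes 57 were higher and 1 lower (median 0.5, adjusted p = 6.1e-06, adjusted p = 0.34 with an estimated correlation). Of 18 markers of alternative activation 13 were lower and 3 higher (median -1.34, adjusted p = 0.00029). Pparg was at 1.2 ± 0.148 against 97.9 ± 8.93 CPM (-6.33 ± 0.14, adjusted p = 2.5e-30). Scaling by library size only shifts this comparison by -0.2, to 3079 genes higher and 6279 lower. Dcn, a fibroblast gene, had no count in untreated cells and 1.56 ± 0.599 CPM with LPS, at least 37-fold more. The stromal and endothelial list had 4 of 6 genes higher with none lower, and its sum stood at 18.7 ± 4.25 in untreated and 35.2 ± 1.86 CPM in LPS-treated cells. Of the sum with LPS, Kdr alone held 22.2 CPM. All 4 lymphocyte markers tested, of 13 in the list, were lower (sums of 166 ± 8.64 and 8.77 ± 1.58 CPM). Dendritic cell markers had 2 higher and 4 lower of 8 (152 ± 26.8 and 15.9 ± 1.74), neutrophil markers 3 and 2 of 11 (10.9 ± 1.51 and 26.8 ± 2.5), and mast cell and basophil markers 1 and 2 of 5 (11.2 ± 0.485 and 1.57 ± 0.951).

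The third question is what dexamethasone did without LPS at 4 h, where it raised 2644 and lowered 3557 genes, 746 and 840 at least 2-fold. Of 18 glucocorticoid targets 13 rose and 3 fell (median 2.24, camera adjusted p = 3.3e-52). Fkbp5, a co-chaperone of the receptor, went from 52.4 ± 0.527 to 1480 ± 4.54 CPM (4.82 ± 0.07, adjusted p = 3e-35), and Tsc22d3 from 37.2 ± 1.47 to 962 ± 17 (4.69 ± 0.07, adjusted p = 4.3e-35). Ddit4, an inhibitor of mTORC1, went from 1.09 ± 0.193 to 394 ± 17.1 (8.53 ± 0.11, adjusted p = 6.3e-37). Cd163, the haemoglobin scavenger receptor, went from 18.1 ± 1.99 to 174 ± 7.77 CPM (3.26 ± 0.09, adjusted p = 1e-25). Mertk, a receptor for apoptotic cells, went from 24.4 ± 3.9 to 230 ± 8.85 (3.22 ± 0.1, adjusted p = 4.6e-18). Tnf fell from 35.6 ± 1.59 to 8.18 ± 1.03 CPM (-2.12 ± 0.09, adjusted p = 1.3e-20). Of 34 interferon-stimulated genes 29 were lower (median -0.69, adjusted p = 4.1e-05, adjusted p = 0.84 with an estimated correlation). Of 20 chemokines 9 were lower and 1 higher (median -1.26, or -0.84 with bounded values, adjusted p = 0.0041, adjusted p = 0.29 with an estimated correlation). Plau, the urokinase gene, fell from 1290 ± 78.7 to 60.3 ± 8.97 CPM (-4.42 ± 0.25, adjusted p = 7.8e-11). Of the markers of other cells, those of stromal and endothelial cells had 1 higher and 3 lower of 6 (sums of 19.2 ± 3.68 and 3.22 ± 0.296 CPM), neutrophils 1 and 4 of 11 (60.8 ± 11.5 and 73.3 ± 5.9), dendritic cells 1 and 3 of 8 (28.9 ± 5.64 and 34.4 ± 3.08), and lymphocytes 0 and 1 of 4 (32.6 ± 3.42 and 16.7 ± 3.02). Mast cell and basophil markers had 2 of 5 lower with none higher (4.79 ± 0.827 and 2.07 ± 0.947). Of the stromal and endothelial sums, Kdr alone held 15.5 ± 3.2 CPM in untreated cells and 0.879 ± 0.236 CPM with dexamethasone.

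The fourth question is the same contrast at 24 h, where 3282 genes were higher and 3977 lower, 716 and 1375 at least 2-fold. Of the glucocorticoid targets 13 rose and 4 fell (median 1.56, camera adjusted p = 3.8e-32). Fkbp5 was at 854 ± 36.3 against 13.6 ± 2.63 CPM (5.98 ± 0.08, adjusted p = 5.9e-37). All 30 cell cycle genes fell (median -2.15, adjusted p = 4.9e-47). Birc5, the survivin gene, was at 3.11 ± 0.286 against 27.2 ± 1.61 CPM (-3.13 ± 0.16, adjusted p = 4.9e-16). All 34 interferon-stimulated genes fell (median -2, adjusted p = 2.7e-19, adjusted p = 0.23 with an estimated correlation). Of 13 genes of MHC class II and co-stimulation 10 fell and 1 rose (median -1.97, adjusted p = 4.1e-12). H2-Aa, an MHC class II chain, was at 41.5 ± 5.45 against 771 ± 75.5 CPM (-4.22 ± 0.18, adjusted p = 8.1e-13). Beside these, dendritic cell markers had 1 higher and 4 lower of 8, with sums of 152 ± 26.8 in untreated cells and 21.6 ± 2.33 CPM with dexamethasone. Lymphocyte markers had 3 of 4 lower (166 ± 8.64 and 72.5 ± 4.02), mast cell and basophil markers 2 of 5 (11.2 ± 0.485 and 0.903 ± 0.307), and stromal and endothelial markers 1 higher and 2 lower of 6 (18.7 ± 4.25 and 7.97 ± 1.33). Cholesterol synthesis genes were lower in 18 of 22 (median -1.08, adjusted p = 1.7e-05, adjusted p = 0.61 with an estimated correlation). Glycolysis genes were lower in 15 of 21 (median -0.52, adjusted p = 0.01, adjusted p = 0.61 with an estimated correlation). Hp, which codes for haptoglobin, went from 0.217 ± 0.123 to 165 ± 19.9 CPM (9.55 ± 0.23, adjusted p = 2.4e-18). Of 11 neutrophil markers 1 rose and 2 fell, and their summed level was 10.9 ± 1.51 and 130 ± 13.7 CPM. With dexamethasone nearly all of it was Mmp8, a collagenase gene (128 ± 13 against 7.21 ± 1.57 CPM, 4.15 ± 0.16, adjusted p = 4.8e-15).

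The fifth question, the first on the stated aim, is what dexamethasone changed under LPS at 4 h. It raised 3581 and lowered 3807 genes, 924 and 1089 at least 2-fold. Tnf did not pass the test, at 1990 ± 42.1 with both and 2020 ± 112 CPM with LPS (-0.02 ± 0.06, adjusted p = 0.83), nor did Acod1, the itaconate-producing enzyme (8670 ± 331 and 10300 ± 128 CPM, -0.25 ± 0.16, adjusted p = 0.21). Il1b was lower, at 1820 ± 38.2 against 6550 ± 486 CPM (-1.85 ± 0.09, adjusted p = 2.3e-15). Also lower were Il10 (76.7 ± 11.7 against 363 ± 21.3, -2.24 ± 0.1, adjusted p = 9.6e-16) and Nos2 (446 ± 20.4 against 1910 ± 92.4, -2.1 ± 0.15, adjusted p = 3.3e-07). The same holds for Ptgs2, the inducible cyclooxygenase (934 ± 86.1 against 6130 ± 128, -2.71 ± 0.11, adjusted p = 7.5e-14) and Cxcl10 (3270 ± 249 against 9780 ± 556, -1.58 ± 0.11, adjusted p = 3.5e-10). Il6 was 464 ± 52.7 against 539 ± 21.4 CPM (-0.21 ± 0.08, adjusted p = 0.023). This Il6 call is lost without LPS library 2 at 4 h (-0.181, adjusted p = 0.097) or without library 1 (-0.203, adjusted p = 0.07) or 2 (-0.138, adjusted p = 0.15) of both treatments at 4 h. Csf3, which codes for the granulocyte growth factor, rose from 14.2 ± 1.35 to 106 ± 10.1 CPM (2.91 ± 0.12, adjusted p = 5.8e-19). Cxcl1, a neutrophil attractant, rose from 311 ± 42 to 869 ± 24.2 (1.48 ± 0.1, adjusted p = 1.3e-11).

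Among the fixed lists at 4 h, chemokines were lower in 15 of 20 and higher in 3 (median -1.38, camera adjusted p = 2.7e-06). All 34 interferon-stimulated genes were lower (median -0.88, adjusted p = 1.4e-08, adjusted p = 0.42 with an estimated correlation). Inflammatory cytokines were lower in 12 of 18 and higher in 2 (median -0.56, adjusted p = 0.00026, adjusted p = 0.13 with an estimated correlation). NF-kB feedback genes were lower in 13 of 18 and higher in 2 (median -0.36, adjusted p = 3e-04, adjusted p = 0.15 with an estimated correlation). Glucocorticoid targets were higher in 12 of 18 and lower in 5 (median 1.37, adjusted p = 1.3e-21). Tsc22d3 was at 269 ± 15.2 against 1.8 ± 0.285 CPM (7.21 ± 0.1, adjusted p = 1.7e-35). Per1, a clock gene (4.06 ± 0.08, adjusted p = 2.7e-30), and Klf9, a transcription factor gene, also rose (133 ± 6.21 against 2.1 ± 0.938 CPM, 5.97 ± 0.12, adjusted p = 1.1e-28). Cholesterol synthesis genes rose in 19 of 22 with none lower (median 1.13, adjusted p = 5.1e-09, adjusted p = 0.33 with an estimated correlation). Among them was Mvd, mevalonate decarboxylase (54.8 ± 8.39 against 10 ± 1.52 CPM, 2.45 ± 0.11, adjusted p = 6.6e-20). Glycolysis genes fell in 16 of 21 and rose in 4 (median -0.45, adjusted p = 0.00033, adjusted p = 0.35 with an estimated correlation). Hk2, hexokinase 2, was at 157 ± 14.5 against 335 ± 29 CPM (-1.09 ± 0.07, adjusted p = 2e-15). Respiratory chain genes were lower in 21, higher in 6 and not called in 38 of 65 (median -0.1, adjusted p = 0.53). None of 13 mitochondrially encoded genes was called (median -0.01, adjusted p = 0.85). Cell cycle genes were higher in 22 of 30 and lower in 7 (median 0.54, adjusted p = 0.0015, adjusted p = 0.5 with an estimated correlation). Scaling by library size only shifts this comparison by 0.22, to 5974 genes higher and 2365 lower. It makes Tnf a call upward (0.202, adjusted p = 0.0049), as it does mt-Co1 (0.16, adjusted p = 0.026) and mt-Cytb (0.212, adjusted p = 0.01), ends that of Il6 (0.006, adjusted p = 0.96) and puts the respiratory chain median at 0.12. Immediate early and heat shock genes had 4 higher and 4 lower of 11, with sums of 1970 ± 130 with LPS and 1100 ± 67.7 CPM with both. Of the markers of other cells, those of stromal and endothelial cells had 1 higher and 3 lower of 6 (170 ± 25 and 121 ± 5.31 CPM), dendritic cells 1 and 4 of 8 (67.8 ± 12.8 and 42.1 ± 5.52), neutrophils 1 and 3 of 11 (151 ± 24.8 and 123 ± 25.4), and lymphocytes 0 and 1 of 4 (23.1 ± 4.18 and 12.7 ± 2.5). Mast cell and basophil markers had 2 of 5 lower with none higher (11.1 ± 1.86 and 6.56 ± 3.16).

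The sixth question is what dexamethasone changed under LPS at 24 h, where 3154 genes were higher and 3391 lower, 1001 and 866 at least 2-fold. Tnf was lower, at 15.9 ± 1.6 against 64 ± 5.24 CPM (-2.01 ± 0.08, adjusted p = 4.9e-21). Also lower were Il1b (222 ± 24.7 against 3190 ± 181, -3.84 ± 0.09, adjusted p = 4.4e-21) and Nos2 (2.03 ± 1.16 against 235 ± 52, -6.85 ± 0.25, adjusted p = 4.8e-10). Acod1 (685 ± 37.7 against 3230 ± 85.9, -2.24 ± 0.17, adjusted p = 3.3e-09) and Ptgs2 (3 ± 0.852 against 95 ± 9.49, -4.98 ± 0.17, adjusted p = 3.7e-15) fell. So did Ccl2, a monocyte attractant (0.866 ± 0.313 against 29 ± 5.73, -5.05 ± 0.4, adjusted p = 6.6e-09), and Arg1, arginase 1 (0.0866 ± 0.0599 against 17.1 ± 3.28, -7.53 ± 0.46, adjusted p = 9.1e-16). Il6 moved the other way, to 6.54 ± 0.817 from 2.23 ± 0.531 CPM (1.54 ± 0.18, adjusted p = 1.1e-07). Il10 was at 1.78 ± 0.724 against 0.778 ± 0.308 CPM (1.18 ± 0.35, adjusted p = 0.0082). The Il10 call is lost without LPS library 3 at 24 h (0.906, adjusted p = 0.051) or library 3 of both treatments at 24 h (0.815, adjusted p = 0.077). Edn1 was at 63.5 ± 8.16 against 1.07 ± 0.201 CPM (5.87 ± 0.12, adjusted p = 5e-28). Cd163 stood at 167 ± 0.321 against 27.8 ± 2.87 (2.59 ± 0.08, adjusted p = 2.6e-23) and Mertk at 278 ± 10.4 against 78.1 ± 6.95 (1.83 ± 0.09, adjusted p = 4.8e-14). Zbtb16, a transcriptional repressor gene, had 3 counts with LPS and 3082 with both, a ratio of 1090 (95% interval 372 to 5280).

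**Figure D1:**
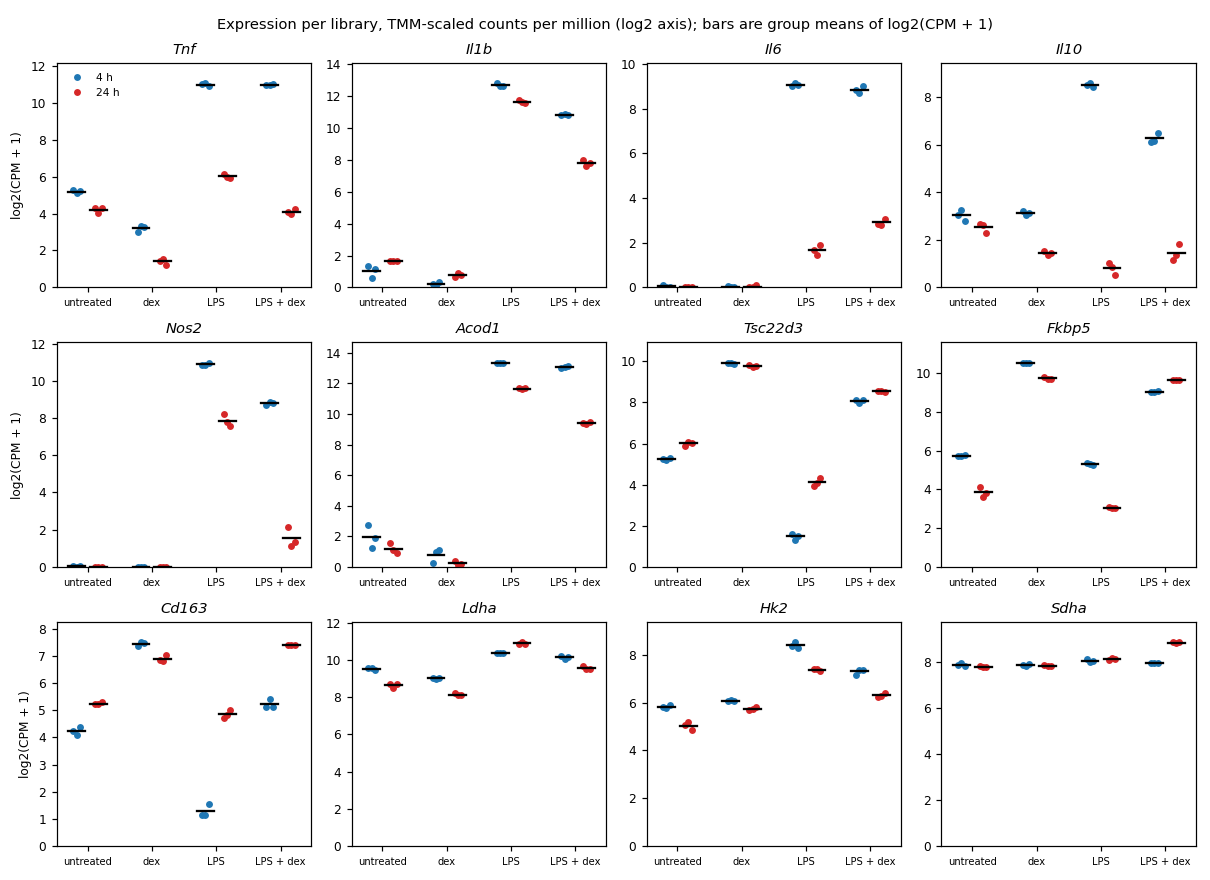
Expression of 12 panel genes in each of the 24 libraries as log2(CPM + 1) on the vertical axis, by treatment on the horizontal axis, with 4 h in blue, 24 h in red and black bars at the mean of the 3 log2 values of a group. With LPS and dexamethasone against LPS, Tnf lies close together at 4 h (1990 and 2020 CPM) and lower at 24 h (15.9 and 64 CPM), while Il10 is lower at 4 h and higher at 24 h.

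Among the metabolic lists at 24 h, glycolysis genes fell in 19 of 21 and rose in 1 (median -1.07, camera adjusted p = 6.2e-24, adjusted p = 0.0033 with an estimated correlation). Ldha went from 1920 ± 58.8 to 765 ± 57.9 CPM (-1.32 ± 0.06, adjusted p = 6e-21) and Hk2 from 164 ± 6.5 to 78.1 ± 4.54 (-1.07 ± 0.07, adjusted p = 7.7e-15). Slc16a3, a lactate exporter, went from 493 ± 44.2 to 73.7 ± 7.55 (-2.74 ± 0.1, adjusted p = 3e-16). Pfkfb3 rose from 1210 ± 86.5 to 1780 ± 161 (0.55 ± 0.07, adjusted p = 9.5e-09). Hypoxia response genes fell in 13 of 14 (median -2.01, adjusted p = 8.6e-25). Vegfa, the vascular growth factor, was at 8.24 ± 1.39 against 138 ± 3.47 CPM (-4.06 ± 0.12, adjusted p = 1.2e-21). Tricarboxylic acid cycle genes rose in 16 of 20 and fell in 2 (median 0.41, adjusted p = 2.2e-05, adjusted p = 0.069 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, was at 454 ± 6.58 against 278 ± 6 CPM (0.71 ± 0.05, adjusted p = 1.8e-15). Pcx, pyruvate carboxylase, was lower at 7.04 ± 0.66 against 14.4 ± 2.38 (-1.04 ± 0.14, adjusted p = 1.8e-07). Nuclear respiratory chain genes rose in 48 of 65 with none lower (median 0.34, adjusted p = 4.3e-08, adjusted p = 0.31 with an estimated correlation). Among them was Ndufv2, a complex I subunit (0.87 ± 0.06, adjusted p = 2.2e-14). Fatty acid oxidation genes rose in 14 of 18 and fell in 1 (median 0.25, adjusted p = 0.029, adjusted p = 0.24 with an estimated correlation). Mitochondrially encoded genes were higher in 10 of 13 (median 0.4, adjusted p = 0.14). Pdha1, the catalytic subunit gene of pyruvate dehydrogenase, went from 75.5 ± 4.36 to 109 ± 5.65 CPM (0.53 ± 0.06, adjusted p = 5.4e-10). Pdk1, a kinase that inhibits this complex, went from 149 ± 11.3 to 51.8 ± 3 (-1.53 ± 0.08, adjusted p = 8.2e-18). The pyruvate dehydrogenase list had 7 of 13 higher and 3 lower (median 0.29, adjusted p = 0.49).

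The remaining lists at 24 h follow. Chemokines fell in 16 of 20 and rose in 2 (median -3.33, or -2.98 with bounded values, camera adjusted p = 1.9e-11). All 34 interferon-stimulated genes fell (median -1.79, adjusted p = 4.6e-27). Ifi44 was at 9.41 ± 1.18 against 122 ± 9.91 CPM (-3.7 ± 0.24, adjusted p = 4.1e-10). Inflammatory cytokines fell in 10 of 18 and rose in 3 (median -0.56, adjusted p = 0.0079, adjusted p = 0.15 with an estimated correlation). Glucocorticoid targets rose in 14 of 18 and fell in 3 (median 1.53, adjusted p = 3.6e-50). Nrf2 response genes fell in 11 of 12 (median -1.28, adjusted p = 4.2e-12). Cell cycle genes rose in 27 of 30 and fell in 1 (median 1.5, adjusted p = 4.6e-17). Ccnb2, a mitotic cyclin, was at 11.2 ± 1.38 against 1.17 ± 0.368 CPM (3.27 ± 0.2, adjusted p = 3.7e-15). Genes of MHC class II and co-stimulation fell in 10 of 13 and rose in 2 (median -0.87, adjusted p = 0.00031, adjusted p = 0.13 with an estimated correlation). Arginine and nitric oxide genes fell in 7 of 10 and rose in 1 (median -0.69, adjusted p = 0.00042). Camera called none of the others, given here as genes higher and lower of those tested. They are NF-kB feedback 3 and 12 of 18, inflammasome 3 and 8 of 12, Toll-like receptor 4 pathway 2 and 9 of 19, alternative activation 8 and 8 of 18. Further ones are uptake of apoptotic cells 9 and 5 of 19, cholesterol synthesis 1 and 8 of 22, eicosanoids 4 and 5 of 11, lysosome 6 and 12 of 25. The rest are circadian clock 3 and 8 of 13, unfolded protein response 6 and 4 of 14, ribosomal proteins 1 and 19 of 40, immediate early and heat shock genes 3 and 8 of 11, and macrophage identity 1 and 5 of 10. Among markers of other cells, neutrophil markers had 2 higher and 2 lower of 11. Their summed level was 103 ± 17.9 against 26.8 ± 2.5 CPM, mostly Mmp8 (82.6 ± 14.9 against 16.9 ± 1.78 CPM, 2.29 ± 0.15, adjusted p = 3.1e-11). Dendritic cell markers had 0 and 2 of 8, lymphocyte markers 1 and 1 of 4, stromal and endothelial markers 0 and 2 of 6, mast cell and basophil markers 0 and 3 of 5, and no erythroid marker was tested.

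**Figure D2:**
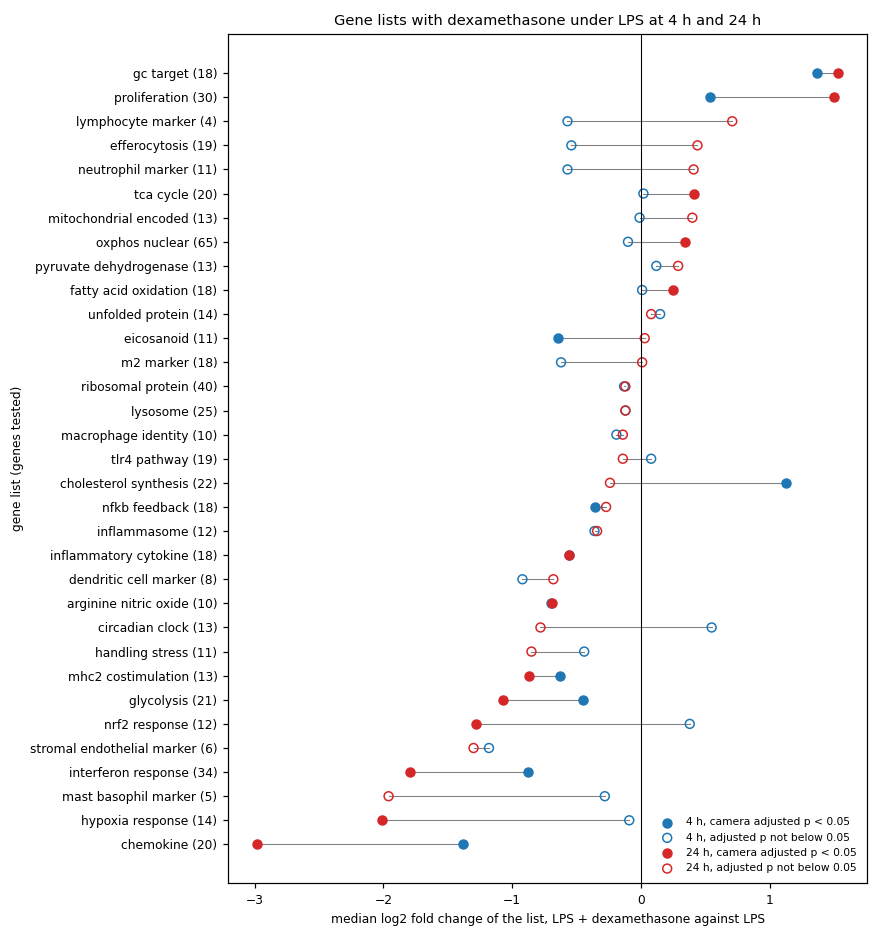
Median log2 fold change of the tested genes of each of 33 fixed lists, with LPS and dexamethasone against LPS, on the horizontal axis, with bounded values for genes with few counts, 4 h in blue and 24 h in red; filled points have a camera adjusted p < 0.05 and grey lines join the 2 times of a list. Chemokines lie at -1.38 and -2.98, glycolysis at -0.45 and -1.07, and the nuclear respiratory chain at -0.1 and 0.34.

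The next question is how far dexamethasone worked against the LPS response. Of 2630 genes that LPS raised at least 2-fold at 4 h, 1468 (55.8%) were lower with dexamethasone, 351 (13.3%) higher and 811 not called, with a median of -0.47. Of the 3249 that LPS lowered, 1292 (39.8%) were higher with dexamethasone and 384 lower (median 0.41). At 24 h, 825 (53.4%) of 1544 LPS-induced genes were lower, among them Tnf, Il1b and Nos2, and 251 (16.3%) higher, among them Edn1 (median -0.56). Further, 801 (38.2%) of 2099 LPS-repressed genes were higher and 281 lower (median 0.39). Of all 14985 tested genes, dexamethasone under LPS lowered 3807 and raised 3581 at 4 h, and lowered 3391 and raised 3154 at 24 h. In 10 simulations without a dexamethasone effect at most 1 gene was induced and lowered, and none was induced and raised or repressed and raised. With no effect to call, few calls were bound to result. The simulations cannot show whether sharing the LPS libraries tilts real dexamethasone calls against the LPS change. The LPS libraries stand in both comparisons, and with scaling by library size only the 4 h counts are 785 induced genes lowered and 3224 repressed genes raised.

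Across the times, the dexamethasone changes under LPS overlap in part. Of the genes raised at 4 h and at 24 h, 1387 are shared against 754 for independent lists, and of those lowered 1791 against 861, with r = 0.41 over all genes. In opposite directions, 1004 genes were called at both times, 459 raised at 4 h and lowered at 24 h and 545 the reverse. Both numbers are below the 1387 and 1791 shared in the same direction, and no expectation for independent lists was computed for them. Of the 1004, 60 were at least 2-fold at both times. These include Il10 (-2.24 and 1.18), Cxcl1 (1.48 and -4.55), Myc, a growth regulator (-1.2 and 2.62), Rgs2, a regulator of G protein signalling (-2.88 and 1.19), and Hspa1a, a heat shock gene (1.46 and -1.67). The Il10 value at 24 h loses its call without library 3 of LPS (0.906, adjusted p = 0.051) or of both treatments (0.815, adjusted p = 0.077). Without LPS, dexamethasone shared 1548 rises between the times against 579 for independent lists and 2105 falls against 944 (r = 0.56). With and without LPS the shared rises were 1175 against 632 at 4 h and 1232 against 691 at 24 h, and the shared falls 1695 against 904 and 1606 against 900, with r = 0.38 and r = 0.32.

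The question put by the labels, whether the dexamethasone effect under LPS differs between the times, was tested as an interaction. The difference was positive for 2846 and negative for 2962 genes, 1004 and 804 at least 2-fold. The dexamethasone effect on Tnf was more negative at 24 h (difference -1.99 ± 0.1, adjusted p = 1.9e-17). The fall of Nos2 (-4.76 ± 0.31, adjusted p = 2.1e-07) and Il1b (-1.99 ± 0.12, adjusted p = 8.8e-13) was larger at 24 h, as was that of Ptgs2 (-2.27 ± 0.22, adjusted p = 7e-08) and Cxcl10 (-3 ± 0.21, adjusted p = 5.2e-10). Il6 (1.76 ± 0.2, adjusted p = 8e-08) and Il10 (3.42 ± 0.37, adjusted p = 3.3e-08) went the other way. Fkbp5 rose more at 24 h (2.98 ± 0.1, adjusted p = 1.2e-22) and Tsc22d3 less (-2.7 ± 0.14, adjusted p = 1.7e-17). Ldha fell more at 24 h (-1.09 ± 0.08, adjusted p = 6.4e-14). Hk2 showed no difference that passed (0.02 ± 0.1, adjusted p = 0.9). The dexamethasone effect on Sdha was more positive at 24 h (0.8 ± 0.07, adjusted p = 1.9e-12), where alone it was a rise. Respiratory chain genes had a positive difference in 47 of 65 and a negative one in none (median 0.43, camera adjusted p = 1.4e-10, adjusted p = 0.24 with an estimated correlation). Glycolysis genes had a negative one in 16 of 21 (median -0.82, adjusted p = 1.7e-09, adjusted p = 0.093 with an estimated correlation). Cholesterol synthesis genes had a negative one in 19 of 22 (median -1.59, adjusted p = 1.9e-12, adjusted p = 0.14 with an estimated correlation). All 12 libraries of 4 h carry Y-linked transcripts and no Xist and all 12 of 24 h the reverse. Time can therefore not be told apart from the sex or batch of the donors, and pseudogene counts also differ between the times. Scaling by library size only shifts the interaction by -0.19, to 1937 genes positive and 4808 negative.

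The same reservation meets the untreated cells, where the question is what changed with time alone. At 24 h against 4 h, 4580 genes were higher and 4552 lower, 2220 and 996 at least 2-fold. Xist, the transcript of the inactive X chromosome, had no count in any 4 h library and 8473 to 15577 in each 24 h library, and Ddx3y, a Y-linked gene, 1448 to 2655 and none. Uty, Kdm5d and Eif2s3y, also Y-linked, had no count at 24 h. Of 1239 tested pseudogenes 964 were higher and 19 lower (median 2.54), against 3254 and 4435 of 12224 protein-coding genes (median -0.07). Pseudogenes held 0.187 to 0.392% of all counts at 4 h and 0.791 to 1.15% at 24 h. The mitochondrial genes mt-Nd4l and mt-Atp6 had 6 to 18 and 114 to 216 counts per library at 4 h and 375 to 874 and 3078 to 6508 at 24 h. All 30 cell cycle genes were lower at 24 h (median -1.21, camera adjusted p = 3.1e-18, adjusted p = 0.092 with an estimated correlation). So were 10 of 11 neutrophil markers (median -3.22, adjusted p = 0.0021, adjusted p = 0.35 with an estimated correlation), whereas 10 of 13 genes of MHC class II and co-stimulation were higher (median 2.07, adjusted p = 4.2e-08, adjusted p = 0.092 with an estimated correlation). Lymphocyte markers had 2 of 4 higher with none lower (sums of 32.6 ± 3.42 at 4 h and 166 ± 8.64 CPM at 24 h). Dendritic cell markers had 1 higher and 3 lower of 8, while their sum stood at 28.9 ± 5.64 and 152 ± 26.8 CPM. Mast cell and basophil markers had 1 higher and 2 lower of 5 (4.79 ± 0.827 and 11.2 ± 0.485), and stromal and endothelial markers 1 and 3 of 6 (19.2 ± 3.68 and 18.7 ± 4.25). Donor, batch and alignment could each stand behind these values, and the design offers no library that separates them.

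**Figure D3:**
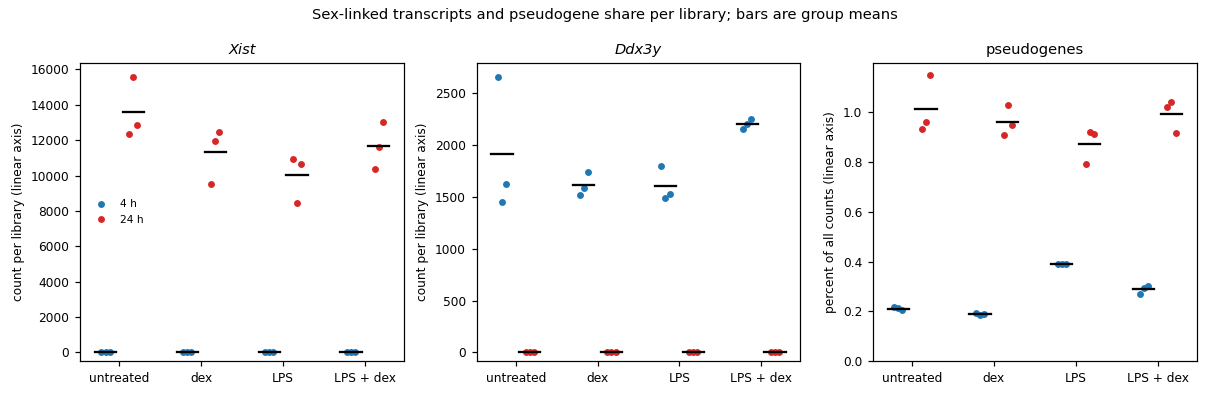
Counts of Xist and of Ddx3y per library, and pseudogenes as percent of all counts per library, on linear vertical axes, by treatment, with 4 h in blue, 24 h in red and black bars at the group means. Xist is 0 in all 12 libraries of 4 h and at least 8473 in all 12 of 24 h, Ddx3y shows the reverse, and pseudogenes lie at 0.187 to 0.392% at 4 h and 0.791 to 1.15% at 24 h.

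The last question is whether LPS changes the response to dexamethasone. At 4 h the dexamethasone effect was more positive with LPS for 3122 genes and more negative for 2675, and at 24 h for 3065 and 2659. Ddit4, raised 8.53 on the log2 scale without LPS at 4 h, had the most negative difference there among genes that meet the naming rule (-8.14 ± 0.16, adjusted p = 3.9e-30). Jaml, an adhesion molecule gene, was also raised less under LPS at that time (-4.79 ± 0.29, adjusted p = 1.4e-14). At 24 h the dexamethasone effect was more positive under LPS for Zbtb16 (7.19 ± 0.41, adjusted p = 2.1e-15) and Sdha (0.67 ± 0.07, adjusted p = 9.2e-11). It was more negative for Hk2 (-1.79 ± 0.1, adjusted p = 4.8e-16) and Ldha (-0.81 ± 0.08, adjusted p = 8.8e-11). For Saa3 it was also more negative (-8.13 ± 0.33, adjusted p = 4.4e-13), though its share of counts did not fall under LPS. Saa3 held 5.48 to 5.94% of the counts with LPS at 24 h and 7.35 to 7.68% with both. Dexamethasone alone raised it from 0.378 ± 0.352 to 134 ± 17.9 CPM (8.48 ± 0.27, adjusted p = 8.8e-15). The LPS effect itself differed between the times for 4617 genes upward and 4568 downward. Examples are Tnf (-3.95 ± 0.11, adjusted p = 1.6e-26), Il10 (-8.26 ± 0.28, adjusted p = 9.7e-19) and Ldha (1.39 ± 0.08, adjusted p = 9.1e-18). The effect of dexamethasone alone differed for 2074 and 2520. Both carry the reservation on sex, batch and pseudogenes between the times. Library size only shifts the first of them by 0.57 (7692 and 2573) and the 4 h contrast with and without LPS by 0.23 (5279 and 1566).

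Positions are as listed in the count table, taken as GRCm39, with the build in doubt. Tnf is ENSMUSG00000024401.15 on chromosome 17 from 35418357 to 35420983, Il1b ENSMUSG00000027398.14 on chromosome 2 from 129206490 to 129213059. Il6 is ENSMUSG00000025746.12 on chromosome 5 from 30218112 to 30224979, Il10 ENSMUSG00000016529.6 on chromosome 1 from 130947582 to 130952711. Nos2 is ENSMUSG00000020826.10 on chromosome 11 from 78811613 to 78851080, Ldha ENSMUSG00000063229.16 on chromosome 7 from 46490899 to 46505051 and Sdha ENSMUSG00000021577.15 on chromosome 13 from 74470373 to 74498399. Adjusted over each list alone, counts moved by at most 2 genes in the comparisons of dexamethasone under LPS. The p-values measure only the spread between these libraries, which may be technical replicates, and say nothing of other mice.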

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

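Chosen after the result was seen were the tests on the share of sex-chromosome genes, the sex of the donors, both scaling tests, the reads of Il10, the stromal markers and the dividing cells, and that on pseudogenes, written down after a few of them had been looked at. What marked these results is a tested difference between the times. The dexamethasone effect under LPS differed for 2846 genes upward and 2962 downward, the LPS effect for 4617 and 4568, and the effect of dexamethasone alone for 2074 and 2520. For dexamethasone under LPS the log2 differences, 24 h minus 4 h, were -1.99 for Tnf, Il1b and Acod1, 1.76 for Il6, 3.42 for Il10, -4.76 for Nos2, -2.27 for Ptgs2, -3.33 for Ccl2 and -3 for Cxcl10. They were -2.7 for Tsc22d3, 2.98 for Fkbp5, 2.19 for Dusp1, -2.31 for Per1, 0.46 for Nr3c1. Further values were -1.09 for Ldha, 0.41 for Pdha1, -1.49 for Pcx, 0.8 for Sdha, -2.07 for Cd163, 0.6 for Mertk and -0.89 for Nlrp3. The list medians of the same difference were 1.07 for glucocorticoid targets, -2.06 for chemokines, -0.82 for glycolysis and 0.44 for the tricarboxylic acid cycle, each with adjusted p = 0.093 with an estimated correlation. They were -0.83 for interferon-stimulated genes (adjusted p = 0.44 with an estimated correlation), 0.6 for uptake of apoptotic cells (adjusted p = 0.1 with an estimated correlation) and 1.06 for the cell cycle (adjusted p = 0.1 with an estimated correlation). The nuclear respiratory chain had 0.43 and fatty acid oxidation 0.32, each with adjusted p = 0.24 with an estimated correlation, and cholesterol synthesis -1.59 (adjusted p = 0.14 with an estimated correlation). Those that passed both ways were -1.7 for hypoxia response (adjusted p = 0.00028 with an estimated correlation), -1.6 for Nrf2 response (0.003) and -0.95 for the circadian clock (0.0074).

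The first pattern weighed is the untreated cells, which differ between the times. Genes on X and Y make up 3.19% of the 9132 genes called there and 3.24% of those tested, and without them 4433 and 4405 genes were called. Only 485 tested genes lie on X or Y, so they could not make up the bulk of 9132 calls whatever the data. The values show only that genes on X and Y were called about as often as the rest. All 24 libraries follow the time in Xist and the Y-linked genes, so that an effect of donor sex on other genes, or of the batch that came with it, stays open. The tested pseudogenes not looked at before had a median log2 fold change of 2.53, which is in line with reads that match several places having been handled differently at the 2 times, before the counting, which was 1 run for all libraries. Time in culture, the biological explanation, was not separable from these.

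The second pattern is that Il6 and Il10 were higher with dexamethasone under LPS at 24 h. Few reads are argued against for Il6, whose lowest library with both treatments had 2.16 times the CPM of the highest LPS library, and stay open for Il10, where this ratio was 1.14. Scaling stays open, since the lowest log2 fold change of both genes over 3 scalings, 1.18, tests little where the other scalings shift all genes by 0.02 and 0.03. Stromal and endothelial markers had a median of -1.3, but of the 6 tested only Pecam1 (-2.14) and Kdr (-4.14) passed, so cells of another type stay open. A dexamethasone effect on these genes is not excluded by any of the tests, though the Il10 call is lost without library 3 of either group.

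The third pattern is respiratory chain genes higher and glycolysis genes lower with dexamethasone under LPS at 24 h. Random lists matched on length and level had a median of -0.07, and 0 of 1000 reached 0.34, which argues against length and level for the respiratory chain. A factor per library shifts all genes alike, so scaling alone cannot give the gap of 1.41 between the 2 list medians. That they lie on opposite sides of 0 is how the pattern was picked and tests nothing. Whether scaling set the sign of the smaller move, the 0.34 of the respiratory chain, stays open. The other scalings shift all genes here by only 0.02 and 0.03. More dividing cells stay open, since with dexamethasone alone at 24 h, where the cell cycle genes fell (-2.15), the respiratory chain median was -0.11 (adjusted p = 0.58), while with LPS at 24 h the medians were -2.63 and 0.5 and with dexamethasone under LPS at 4 h 0.54 and -0.1. A dexamethasone effect on metabolism is the biological explanation and was not separated from that of division.

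In splits of the 6 libraries of a comparison, 10 are too few for a share under 0.05, and 1 of 10, the real one, called as many genes in each. The real counts and the highest of the others were 10930 and 3 for LPS at 4 h and 9046 and 0 at 24 h. They were 6201 and 1 for dexamethasone at 4 h, 7259 and 0 at 24 h. They were 7388 and 5 for dexamethasone under LPS at 4 h, 6545 and 1 at 24 h, and 9132 and 0 for the untreated cells. Each of the other splits mixes libraries of both groups, which widens the spread within a group for every gene that differs. Their low counts are therefore no measure of chance. Of 20 assignments for the LPS genes, 1 gave as many induced genes lowered (1468, highest other 671, at 4 h, and 825 and 744 at 24 h). There 2 gave as many raised (351 and 924, 251 and 314) and 1 as many repressed genes raised (1292 and 857, 801 and 625). The 20 are the 10 splits taken in both directions, so the highest other is the real split with the names of the 2 groups exchanged. The remaining splits called at most 5 genes between these groups at 4 h and 1 at 24 h. The highest others are therefore no measure of chance. For the interactions, fitted here on only the 12 libraries concerned so that the real counts differ from those above, 1 of 21 gave as many genes. The shuffled groups mix libraries of both times, or with and without dexamethasone. Their counts thus hold effects other than an interaction, and this share is no measure of chance. The counts were 5471 against 4662 for dexamethasone under LPS by time, 9049 against 6137 for LPS by time, 4929 against 4232 for dexamethasone alone by time. They were 5242 against 1931 and 6602 against 2732 for LPS by dexamethasone at 4 h and 24 h.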

How the results depend on the processing

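Fits without X and Y, without pseudogenes and with the libraries of 1 time were chosen after the result was seen, and all others before the data were examined. Depth can limit genes with few counts, and the 3 libraries of a group the rest, but neither was tested. Replicate numbers are not said to pair libraries. Over 84 same-numbered pairs the correlation of deviations from the group means averaged -0.0027, against 0.0012 for other pairs, with 9 over 0.1, and 7 of 24 libraries had their best partner under the same number. With replicate number as a replicate block, 10850 of 10930, 8966 of 9046, 6073 of 6201, 7156 of 7259, 7262 of 7388, 6429 of 6545 and 5715 of 5808 calls were kept. These are LPS, dexamethasone and dexamethasone under LPS at 4 h and 24 h, and the last by time. DESeq2 kept 10600, 8936, 6078, 7118, 7172, 6308 and 5486. Without X and Y the dexamethasone effect under LPS differed between the times for 2752 and 2888 genes, and without pseudogenes for 2801 and 2910. The untreated cells then gave 4433 and 4405, and 3965 and 4104. With the libraries of 1 time only, dexamethasone under LPS gave 3461 and 3324 at 4 h and 3384 and 3792 at 24 h. Of 1107 values of named genes, library size only reversed the sign of 21, some of which no longer passed, ended 18 further calls and added 7. The other alternatives reversed none, ended 3 to 10 and added 1 to 8, and with only the libraries compared 25 had no value, as the gene was not tested there. The 24 fits that each leave out 1 library ended 165 calls and added 18 in total, counted once per fit. All counts of genes stayed within 1.5 times under RLE factors, DESeq2, robust estimation off, the block, only the libraries compared and each library left out.

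With library size only, which takes no account of composition, counts higher and lower moved to 2434 and 9779 for LPS at 4 h and 5974 and 2365 for dexamethasone under LPS at 4 h. The interactions moved to 7692 and 2573 for LPS by time, 5279 and 1566 for LPS by dexamethasone at 4 h, and 4808 lower for dexamethasone under LPS by time. Induced genes lowered at 4 h were 785, repressed genes raised 3224, and calls shared between the times 2109 higher and 1173 lower. Directions turned by construction of the shift for LPS at 4 h in Sdha (-0.6), Mertk (-0.653), Dlst (-0.246), Cs (-0.262), mt-Co1 (-0.39), mt-Nd1 (-0.421), Srebf2 (-0.389), Cenpe (-0.305), Ube2c (-0.315) and Rpl27 (-0.067). They turned at 24 h in mt-Co1 (-0.042) and Rps9 (-0.036), and for dexamethasone under LPS at 4 h in Tnf (0.202), Il6 (0.006), Sdha (0.129), mt-Co1 (0.16) and mt-Cytb (0.212). For LPS by time they turned in Fkbp5 (0.139), Hk2 (0.349) and Mertk (0.507), and for LPS by dexamethasone at 4 h in Sdha (0.158). Some of these turned in sign but no longer passed. They are Rpl27 (adjusted p = 0.28), mt-Co1 (0.56) and Rps9 (0.55) at 24 h, Il6 (0.96) and Fkbp5 (0.28).

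With a minimum of 2-fold, fewer genes pass by construction. Higher and lower were 2630 and 3249 for LPS at 4 h, 1544 and 2099 at 24 h, 746 and 840 for dexamethasone at 4 h, and 716 and 1375 at 24 h. They were 924 and 1089 for dexamethasone under LPS at 4 h, 1001 and 866 at 24 h, and 2220 and 996 for untreated cells. The interactions gave 1004 and 804, 2370 and 2516, and 313 and 862 by time, and 923 and 844 at 4 h and 1262 and 653 at 24 h for LPS by dexamethasone. With no fold minimum for LPS genes, induced lowered, induced raised and repressed raised were 2453, 725 and 2301 at 4 h and 1964, 753 and 1580 at 24 h. Of 231 list tests 79 passed, against 31 with an estimated correlation, 191 with fry and 119 with no filter, and the cause was not tested. The tricarboxylic acid cycle list at 4 h with LPS reversed in direction with fry (median log2 fold change 0.026, fry adjusted p = 0.023), and the cause was not tested.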

Other observations

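The test on mt-Atp8 and that on nuclear copies were written down before their values were seen, though the pattern itself was found in the data. At 4 h, LPS lowered Cnr2, a cannabinoid receptor gene, from 37.3 ± 2.34 to 0.207 ± 0.0802 CPM (log2 fold change -7.44 ± 0.17, adjusted p = 1.4e-30). Dexamethasone under LPS at 4 h lowered Ch25h, whose product makes 25-hydroxycholesterol, from 369 ± 25.7 to 13.7 ± 2.7 CPM (-4.75 ± 0.19, adjusted p = 1.3e-13), and raised Tns1, a focal adhesion gene, from 3.87 ± 0.649 to 422 ± 35 CPM (6.76 ± 0.17, adjusted p = 1.2e-17). At 24 h it raised Sult1a1, a sulfotransferase gene, from 0.477 ± 0.114 to 194 ± 17.5 CPM (8.66 ± 0.19, adjusted p = 5.3e-21) and lowered Serpinb2, a protease inhibitor gene, from 105 ± 15.1 to 0.312 ± 0.187 CPM (-8.36 ± 0.21, adjusted p = 4.3e-24).

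The mitochondrial genes mt-Atp6, mt-Atp8 and mt-Nd4l were low in all 4 h libraries, with log2 fold changes of 4.94, 4.92 and 6.47 in untreated cells at 24 h against 4 h, and 0.71 for mt-Nd4. The value of 4.92 for mt-Atp8, with mt-Atp6 moving alike, leaves another library or sequencing batch open. The 6 tested nuclear copies had a median of 5.06 (1.55 to 5.49). An opposite move was set beforehand as the sign of shared reads, which was wrong by the way of counting. Reads that the alignment marked as matching several places were counted at neither time. Such reads do not pass from a gene to its copy but are missing from both. Whether reads were marked alike, and as many lost, at both times depends on read length and alignment settings. The labels do not give these, so shared reads stay open.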
